A study of Camellia oleifera with 221 samples.

How the data were processed

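RNA of seed kernels from 221 Camellia oleifera cultivars was sequenced, 1 library per cultivar. Camellia oleifera is an evergreen tree grown for the oil in its seeds. Per the labels' protocols, the trees were 12 years old and grew outdoors in Hangzhou, kernels were frozen on dry ice, RNA was extracted with Trizol, and libraries were made with an Illumina TruSeq RNA kit. Cultivars are called accessions here and are named as in the labels, where every name starts with assoL; the series tong, minyou, xiang, gan and others are the letters that follow. The labels give no trait, treatment, batch, date or kinship.

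The authors deposited 1 table of FPKM values (fragment counts scaled by gene length and sequencing depth) with 11063 genes and 221 columns, each of which matched 1 accession by name. The submitters' processing notes name the aligner Bowtie 0.12.2 and the build mm8, which is the name of a mouse build and does not match the scaffold names inside the gene identifiers. The genome build and annotation behind the identifiers are not given in the sources used here. The table's lowest gene mean was 1.55 FPKM, so genes of lower mean are not analysed here. Identifiers consist of a gene predictor, a scaffold and a gene number, and the files do not pair them with gene names. The gene lists of seed oil and other pathways that had been fixed beforehand, and both results planned on them, were therefore not used here.

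The authors also deposited 1 file per accession, read here as signal values in an unstated unit. Each value equalled the FPKM of that gene and accession times 1 factor per accession, to within a relative deviation of 3.88e-05. The factor ran from 28.0 to 80.4 with a median of 44.0. Values of 150 low genes stepped in multiples of 1 amount per gene more clearly with each accession's own factor than with shuffled factors, with median step scores of 4.16 and 1.79, and 92% of these genes scored higher with their own factors. The factor was therefore used as a relative depth and is called the depth factor. Gene lengths were not used here, so whole reads were not recovered, the absolute depth is unknown, and no count-based test was run.

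Accessions were grouped by the letters or the digit pattern of their names, the only grouping that the labels hold; what the letters stand for is not assumed. The 6 name series with at least 6 accessions were compared: 134 accessions named by 1 to 3 digits, called the numbered accessions, 15 of tong, 12 of minyou, 9 of xiang, 8 named by 4 digits and 7 of gan. Values were transformed as log2(FPKM + 1), and fold changes on this scale understate the change of low genes. limma 3.58.1 in R 4.3.3 fitted 1 model to the 185 accessions with a mean-variance trend, with Benjamini-Hochberg adjusted p and a threshold of 0.05. All adjusted p-values of single genes come from limma. Tests of single values used 100000 resamples for main values and 10000 for alternatives and are called permutation tests. Each accession is 1 sample, so p-values measure the spread between accessions and not that of repeated measurements. The planned tests, the series, most alternatives and the rule for named genes were chosen before the data were examined; exceptions are named where they are described. By that rule the genes named are the 2 with the highest and the 2 with the lowest log2 fold change per comparison, among those past the threshold with a median of at least 1 FPKM in either group. Over the panel they are the 2 with the highest mean and the 2 with the highest SD of log2 values at a mean of at least 10 FPKM.

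Co-expressed sets were a choice made after the data were seen. They are groups of at least 7 genes linked by Pearson correlations above 0.9 over all 221 accessions, found without use of the series. A set's score is the mean of its genes' deviations from their panel means in log2(FPKM + 1). Set scores were compared by 2-sided permutation tests, adjusted over 25 comparisons of 5 sets in 5 series. These tests take the spread as equal in both groups, so p may be too small where a small series had the larger SD. With the depth factor as a covariate, the residuals of the fit on that factor alone were permuted. The group of 133 genes silent in part of the panel is given as a percent of all genes. At an unadjusted p below 0.05 limma gave 1436 genes for gan and 536 for the names of 4 digits. The comparisons by gene abundance, gene position and depth were also chosen after the data were seen.

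Depth as a covariate, the alternatives for set scores and for the first component, and the couples on partly silent genes were added after the data were seen. The alternatives were other pseudocounts, a minimum mean FPKM, quantile normalization, covariates for the share of abundant genes, for depth and for the first 2 principal components, array weights, no mean-variance trend, and leaving out 29 accessions whose median correlation with the others lay more than 3 median absolute deviations below the panel median. limma was tested on simulated data of the same 11063 genes, with log2 changes of 0.5 and 1 in 100 genes each. Each gene was drawn independently, so the simulation holds none of the co-expression of the real genes. It recovered 68% and 95% of them for tong, 60% and 91% for minyou, 50% and 91% for xiang, 42% and 84% for gan, and 38% and 83% for the names of 4 digits. Calls among the unchanged genes numbered 5, 10, 7, 16 and 4 in the same order. Random splits of the real accessions into series of the same sizes gave up to 370, 5, 454, 135 and 2 genes. The simulated false calls are therefore no measure of those in the real data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for all other steps.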

Results

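Gene expression in the seed kernel was measured in cultivars of Camellia oleifera, collected as a panel for association of transcripts with traits. The largest name series was that of accessions named by 1 to 3 digits, called the numbered accessions. The other series tested were tong with 15, minyou with 12, xiang with 9, names of 4 digits with 8 and gan with 7 accessions, and 36 accessions had names of smaller series. Between 10285 and 10929 of the 11063 genes reached 1 FPKM in an accession, and 7983 genes did so in every accession. The depth factor averaged 44.1 ± 5.84 (SD over the panel). Correlations of log2 profiles between accessions ran from 0.686 to 0.968, with a median of 0.892, and no accession appeared as a copy of another.

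A few very abundant genes dominated the kernel transcriptome, and their level differed widely between accessions. An accession's 20 most abundant genes held 32.9 ± 11.2% (SD over the panel) of its FPKM total, with extremes of 9.93% and 58.02%. The most abundant gene, augustus_masked-HiC_scaffold_2-processed-gene-1682.40 on scaffold 2, averaged 43276 ± 27916 FPKM (SD over the panel) and ranged from 377.6 to 124151 FPKM. The next, maker-HiC_scaffold_6-snap-gene-879.26 on scaffold 6, averaged 20836 ± 13840 FPKM (SD over the panel) with a range from 41.9 to 55875 FPKM. The largest log2 SDs among genes of at least 10 FPKM were 3.21 for maker-HiC_scaffold_2-snap-gene-324.34, which ran from 1.91 to 26442 FPKM, and 3.17 for maker-HiC_scaffold_2-snap-gene-388.4, which ran from 1.19 to 19308 FPKM. Over all genes the median SD was 0.42 in log2 units, and 774 genes had an SD above 1. The files do not pair these identifiers with names.

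The main axis of variation in the panel followed the share of the abundant genes. The first principal component held 24.4% of the variance and the second 11.7%. The first component correlated with the share of the 20 most abundant genes with Pearson's r = 0.893 and Spearman's rho = 0.877 over all accessions. Both permutation p-values were 1e-05, the smallest that the permutations can give, and 1.5e-05 when adjusted over 6 relations. The relation held without the 2 accessions farthest from the median share (r = 0.891) and within the numbered accessions (r = 0.842). Towards the high end of the component 358 genes were higher (r above 0.5), among them 11 of the 20 most abundant genes of the panel, and 2376 genes were lower (r below -0.5). The component was not related to the depth factor, with r = -0.051 (permutation p = 0.447, adjusted p = 0.447) and rho = -0.045 (permutation p = 0.508, adjusted p = 0.508). The second component was related to the depth factor, with r = 0.296 and rho = 0.326, both with permutation p = 1e-05, the smallest possible, and adjusted p = 1.5e-05. It had r = 0.308 without the 2 farthest accessions and r = 0.322 within the numbered accessions.

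**Figure D1:**
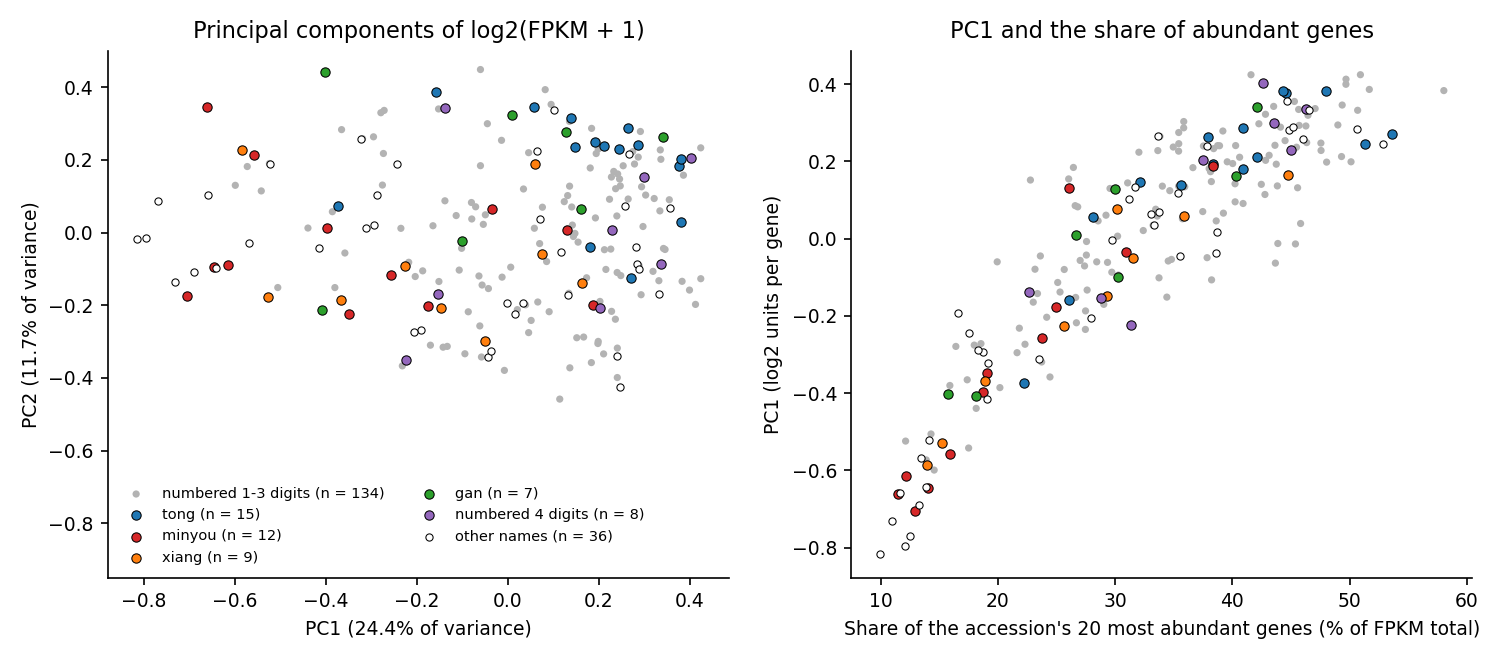
Left, first against second principal component of log2(FPKM + 1) for all accessions, each a point coloured by name series. Right, first component against the share of the accession's 20 most abundant genes in percent of its FPKM total; the points rise together (r = 0.893), with minyou accessions largely at low shares.

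Some genes formed tightly co-varying sets, most of which spanned several scaffolds. There were 2375 gene pairs with r above 0.9 over the accessions, from 602 genes, and 83.7% of the pairs joined different scaffolds. Of the 5 sets with at least 7 genes, set 1 held 130 genes on 15 scaffolds, set 2 held 27 genes on 12 scaffolds, set 3 held 25 genes on 11 scaffolds, set 4 held 9 genes on 7 scaffolds and set 5 held 7 genes on 2 scaffolds. Set 5 consisted of abundant genes, with gene means from 3544 to 43276 FPKM. All but 879.26 of scaffold 6 lie on scaffold 2, where 1681.9, 1682.40, 1682.45 and 1683.30 are close in the gene index and 324.34 and 388.4 lie elsewhere. Set 5 is thus largely local to 1 scaffold. Its genes took 21.1% of the FPKM total on average, from 0.238% to 50.4% between accessions. Set 5 rose along the first component (r = 0.90), while set 1 (r = -0.932) and set 4 (r = -0.871) fell along it. Set 2 followed the second component (r = -0.866), and set 3 was tied less to either (r = -0.406 and r = 0.178). Sets 2 and 3 were related to the depth factor by both r and rho. Set 3 had r = 0.236 (permutation p = 0.00044, adjusted p = 0.0022) and rho = 0.308 (permutation p = 1e-05, the smallest possible, adjusted p = 5.0e-05), r = 0.292 without the 2 farthest accessions and r = 0.114 within the numbered accessions. Set 2 had r = -0.175 (permutation p = 0.00882, adjusted p = 0.022) and rho = -0.208 (permutation p = 0.00195, adjusted p = 0.00487), r = -0.165 without the 2 farthest accessions and r = -0.262 within the numbered accessions. Sets 1, 4 and 5 had r = 0.109, 0.069 and -0.133 (permutation test, adjusted p = 0.13, 0.307 and 0.0794) and rho = 0.151, 0.131 and -0.158 (permutation test, adjusted p = 0.0313, 0.0528 and 0.0313). These 5 sets were defined on the same panel, and their members may share reads where they are near-identical copies, which was not examined without sequences. The median correlation of gene pairs within a set ran from 0.839 in set 2 to 0.914 in set 5. Members of a set are therefore not independent, and counts of its genes called by limma add little to its score.

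A further group, 1.20% of the genes, was expressed in part of the panel and silent in another part. Each reached 1 FPKM in at least 10% of the accessions and stayed below 0.1 FPKM in at least 10%. The median gene of this group was expressed in 53.4% and silent in 18.1% of the accessions, with a median level of 3.75 FPKM where expressed, and 16 of these genes reached 100 FPKM in some accession. Set 1 contained 22 of them. Their share was highest on scaffold 3, with 2.27% of its genes, and lowest on scaffold 4, with 0.183%. Neither departed from the other scaffolds after adjustment over 15 scaffolds (Fisher's exact test, adjusted p = 0.0802 and 0.113).

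The name series differed in their expression profiles, though most of the variation lay within series. The series accounted for 8.74% of the squared distances among their accessions, against a mean of 2.72% with permuted names (one-sided permutation test, p = 1e-05, the smallest possible), and for 5.10% with the first 2 components removed (permutation p = 1e-04, the smallest possible with fewer resamples). The limma F test found differences among the 6 series for 4472 of 11063 genes. On the first component the series accounted for 19.5% of the variance (permutation p = 1e-05, the smallest possible). The number of genes was 2231 with the first 2 components as covariates and 2516 without the 29 accessions of low correlation.

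**Figure D2:**
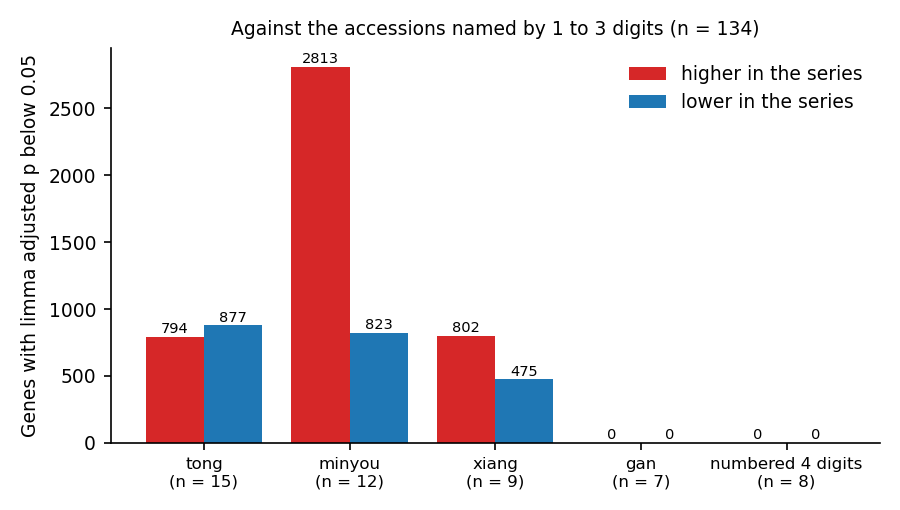
Number of genes with a limma adjusted p below 0.05 in each name series against the numbered accessions, split by direction. Bars start at 0; minyou has 2813 higher and 823 lower genes, and gan and the names of 4 digits have 0.

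The minyou accessions had far less of the abundant transcripts of set 5 than the numbered accessions. All 7 genes of set 5 were lower by limma, and the set's score differed from the numbered accessions by -3.62 log2 units (SE 0.70; 11 of 12 accessions below the numbered median; permutation test, adjusted p = 8.3e-05). Sets 1 and 3 moved the other way. In set 3, 25 of 25 genes were higher, with a score 2.55 above (SE 0.43; 12 of 12 accessions; permutation test, adjusted p = 8.3e-05). In set 1, all but 14 of the 130 genes were higher, with a score 1.22 above (SE 0.46; 10 of 12 accessions; permutation test, adjusted p = 0.0031), and in set 4, 9 of 9 were higher, with a score 1.16 above (SE 0.36; permutation test, adjusted p = 0.00539). In set 2, 8 of 27 genes were higher, and its score did not differ (permutation test, adjusted p = 0.127), but it passed with the depth factor as a covariate (1.03 above, permutation test, adjusted p = 0.03). The set 3 difference was 2.45 with that covariate (permutation test, adjusted p = 0.000833). Of the 100 most abundant genes of the panel, limma called 26 lower and 15 higher, where over all 11063 genes it called 823 lower and 2813 higher. The other 59 did not pass in either direction. The share called was 41%, against 32.8% of the other genes (Fisher's exact test, p = 0.0873). In xiang, limma called 9 of these 100 genes lower and 13 higher, 22% against 11.4% of the other genes (Fisher's exact test, unadjusted p = 0.00245). For tong it called 15 lower and 5 higher, 20% against 15.1% (Fisher's exact test, unadjusted p = 0.163). Fisher's test takes genes as independent, which co-expressed genes are not, so these p-values may be too small.

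The 2 genes most reduced in minyou were maker-HiC_scaffold_2-snap-gene-388.4 and maker-HiC_scaffold_2-snap-gene-324.34. Gene 388.4 averaged 358.2 ± 773 FPKM (SD, n = 12) against 4100 ± 3769 FPKM in the numbered accessions, a log2 fold change of -5.71 (SE 0.72, limma adjusted p = 1.56e-10). Its medians were 15.6 and 2592 FPKM, and its highest minyou value was 2717 FPKM. Gene 324.34 averaged 583 ± 1324 FPKM against 5670 ± 5173 FPKM, a log2 fold change of -5.65 (SE 0.73, limma adjusted p = 4.98e-10). Its medians were 18.7 and 4025 FPKM, and its highest minyou value was 4671 FPKM. Both lay below the numbered median in 11 of 12 accessions. Without the accessions of low correlation their fold changes were -3.62 and -3.47 and still passed. They were -2.81 and -2.69 with the share of abundant genes as a covariate, and -2.84 and -2.70 with the first 2 components. Both genes belong to set 5, whose score followed that share (r = 0.909) and the first component, so these covariates hold part of the tested difference and are no independent check of it. The largest increases were in genes of set 3 and are not independent of its score. They were 4.09 (SE 0.54, limma adjusted p = 8.6e-10) for augustus_masked-HiC_scaffold_12-processed-gene-1524.55, with a mean of 180.4 against 13.3 FPKM, and 3.82 (SE 0.40, limma adjusted p = 5.19e-14) for augustus_masked-HiC_scaffold_3-processed-gene-343.20, with a mean of 149.8 against 4.65 FPKM.

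In all, 3636 genes differed between minyou and the numbered accessions, 2813 higher and 823 lower, and 403 and 94 of these by more than 2-fold. The median log2 fold change of all genes was 0.11, and -0.04 after quantile normalization, which gave 1516 higher and 2030 lower genes. Minyou accessions also had a lower share of their 20 most abundant genes (20.7 ± 8.33% against 34.8 ± 10.04%; permutation test, adjusted p = 7.5e-05) and a higher depth factor (47.6 ± 4.61 against 43.2 ± 5.42; permutation test, adjusted p = 0.0283). With that share as a covariate 1040 genes differed, 447 higher and 593 lower, and with the first 2 components as covariates 1237, 592 higher and 645 lower. Without the accessions of low correlation, 6 of which are minyou, 756 genes differed. Sets 3 and 5 still differed by 2.28 and -2.25 (permutation test, adjusted p = 0.000833 and 0.00312). Sets 1 and 4 no longer did (0.52 and 0.70, permutation test, adjusted p = 0.407 and 0.333). Of those left out, assoLminyou1, assoLminyou2, assoLminyou8, assoLminyou10 and assoLminyou11 lay at -0.557 to -0.705 on the first component. Sets 1 and 4 fall along that component. Leaving these accessions out therefore takes away part of the tested difference and is no independent check of it.

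**Figure D3:**
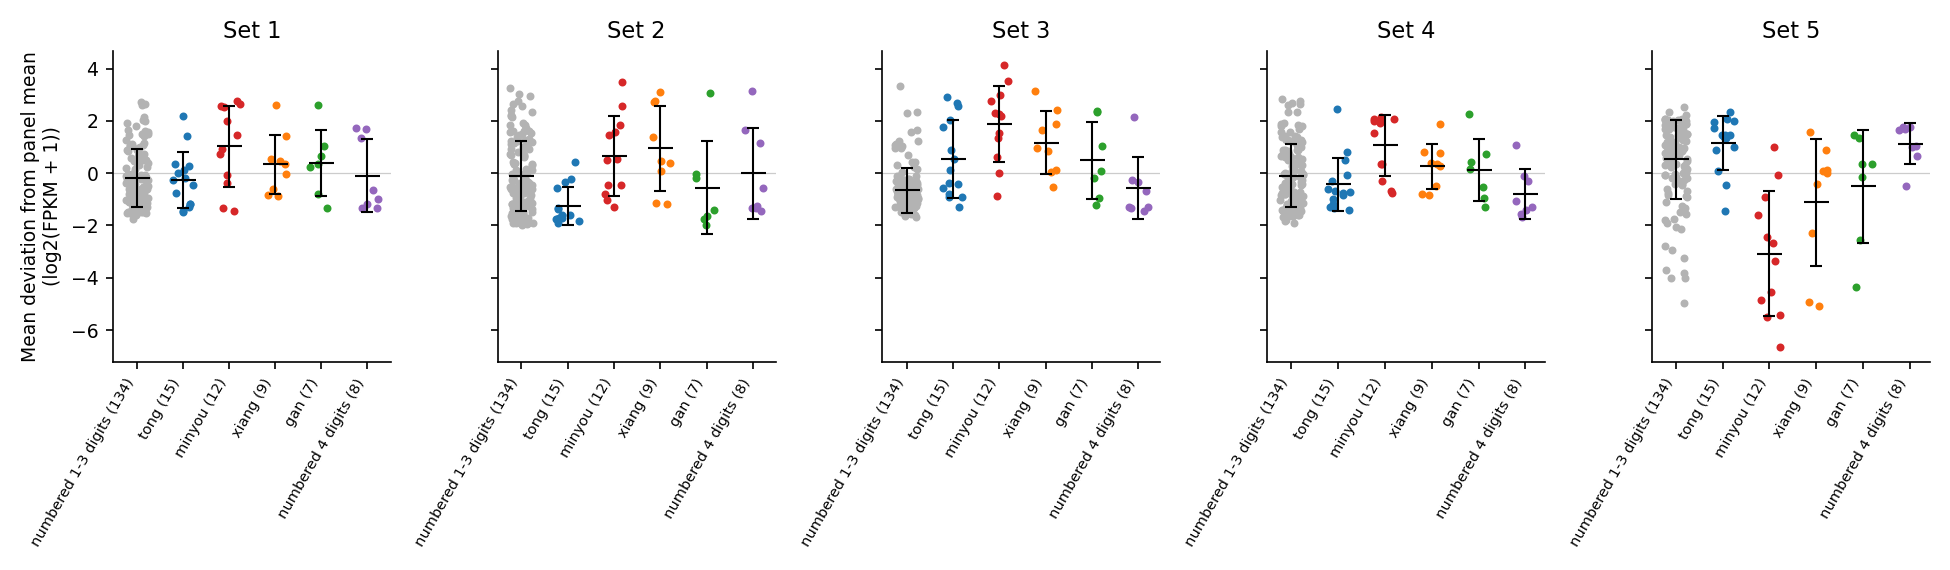
Scores of the 5 co-expressed sets, as the mean deviation of each set's genes from the panel mean in log2(FPKM + 1), for each accession of 6 name series. Bars give the mean and SD; set 5 is lowest and set 3 highest in minyou.

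The xiang accessions also had more of set 3 and less of set 5 than the numbered accessions. All 25 genes of set 3 were higher, and the score lay 1.83 above (SE 0.41; 9 of 9 accessions above the numbered median; permutation test, adjusted p = 8.3e-05). In set 5, 3 of 7 genes were lower, and the score differed by -1.65 log2 units (SE 0.82, 8 of 9 accessions, permutation test, adjusted p = 0.0133). The SD of this score was 2.44 in xiang against 1.51 in the numbered accessions, so this p may be too small. The set 5 difference was -0.79 (permutation test, adjusted p = 0.219) without the accessions of low correlation. The xiang accessions so left out, assoLxiang3 and assoLxiang5, had set 5 scores of -5.09 and -4.92. Leaving them out therefore takes away part of the tested difference. With the depth factor as a covariate set 3 was 1.78 above (permutation test, adjusted p = 0.000833), and set 2 passed as well (1.22 above, permutation test, adjusted p = 0.0192), which it did not without (adjusted p = 0.0542). The largest increases were in augustus_masked-HiC_scaffold_12-processed-gene-1524.55, with 92.7 ± 79.7 FPKM (SD, n = 9) against 13.3 ± 37.2 FPKM (log2 fold change 3.54, SE 0.62, limma adjusted p = 4.73e-05), and augustus_masked-HiC_scaffold_12-processed-gene-1493.24, with 35.6 ± 28.5 against 4.33 ± 10.8 FPKM (log2 fold change 3.24, SE 0.53, limma adjusted p = 1.57e-05). Both belong to set 3, so they are not independent of its score, and both lay above the numbered median in 9 of 9 accessions. Their order turned with pseudocounts of 0.1 and 0.01, where 1524.55 had 3.95 and 4.01 and 1493.24 had 4.19 and 4.48.

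The lowest fold changes in xiang were -2.42 (SE 0.82, limma adjusted p = 0.0375) for maker-HiC_scaffold_2-snap-gene-388.4, below the numbered median in 8 of 9 accessions, and -2.24 (SE 0.76, limma adjusted p = 0.0379) for augustus_masked-HiC_scaffold_2-processed-gene-1682.45, below it in 6 of 9. Both lost significance without the accessions of low correlation (-1.10 and -1.43, limma adjusted p = 0.392 and 0.215). They did not pass with the share of abundant genes (-0.86 and -0.87, limma adjusted p = 0.218 and 0.232) or the first 2 components as covariates (-0.85 and -0.67, limma adjusted p = 0.291 and 0.382), but both belong to set 5, which the covariates follow, so this is no independent check either. In all 1277 genes differed, 802 higher and 475 lower, and 15.5% of the higher and 8.21% of the lower ones by more than 2-fold. The split was 684 higher and 910 lower after quantile normalization, 445 and 679 with the share of abundant genes as a covariate, and 611 and 846 with the first 2 components as covariates. Without the accessions of low correlation 666 genes differed. Whether minyou and xiang differ from each other was not tested.

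The tong accessions had less of set 2 and more of set 3 than the numbered accessions. In set 2, 20 of 27 genes were lower, and the score differed by -1.15 log2 units (SE 0.22; 12 of 15 accessions below the numbered median; permutation test, adjusted p = 0.00539), and by -0.95 with the depth factor as a covariate (permutation test, adjusted p = 0.0192). In set 3, 24 of 25 genes were higher, and the score lay 1.20 above (SE 0.39; 14 of 15 accessions; permutation test, adjusted p = 0.000625). Scores of sets 1, 4 and 5 did not differ (permutation test, adjusted p = 0.825, 0.428 and 0.22), and none of their genes passed the limma threshold. Comparisons against the same numbered accessions are not independent of each other, so the recurrence of set 3 in 4 series, gan included, is not read as a shared effect.

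Among the increases in tong was maker-HiC_scaffold_12-snap-gene-827.5, with 84.8 ± 50.4 FPKM (SD, n = 15) against 21.2 ± 34.5 FPKM, a log2 fold change of 2.40 (SE 0.48, limma adjusted p = 0.000328). Another was augustus_masked-HiC_scaffold_3-processed-gene-1044.6 of set 3 with 2.06 (SE 0.40, limma adjusted p = 0.000188), above the numbered median in 15 of 15 accessions. Their order turned with pseudocounts of 0.1 and 0.01, where 827.5 had 2.51 and 2.52 and 1044.6 had 3.09 and 3.66. The lowest fold changes were -1.98 (SE 0.46, limma adjusted p = 0.0016) for maker-HiC_scaffold_6-snap-gene-650.26 and -1.90 (SE 0.45, limma adjusted p = 0.00179) for augustus_masked-HiC_scaffold_7-processed-gene-771.12. With the first 2 components as covariates, 827.5, 650.26 and 771.12 no longer passed (0.83, -0.24 and -0.83, limma adjusted p = 0.108, 0.446 and 0.157); 650.26 belongs to set 2, which the second component follows. In all 1671 genes differed, 794 higher and 877 lower, of which 69 and 61 by more than 2-fold. With the share of abundant genes as a covariate the split was 1213 higher and 707 lower. The total was 1079 with the depth factor as a covariate, 325 with the first 2 components as covariates and 3350 with array weights.

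No single gene separated gan or the names of 4 digits from the numbered accessions. limma called 0 genes in both, with 1436 genes or 12.98% at an unadjusted p below 0.05 for gan (n = 7) and 4.84% for the names of 4 digits (n = 8). As a set, however, set 3 was higher in gan by 1.15 (SE 0.56, 5 of 7 accessions above the numbered median, permutation test, adjusted p = 0.0121). The SD of its score was 1.47 in gan against 0.87 in the numbered accessions. The permutation test takes these spreads as equal, so this p may be too small and the difference is not secure. Array weights gave 371 genes for gan. None of the 5 sets differed for the names of 4 digits (permutation test, lowest adjusted p = 0.212).

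Accessions with matching names were compared to ask whether a shared name goes with a shared profile. The 7 couples were assoL213 with assoL213-1, assoL164 with assoL164-1, assoLwu with assoLwu-1, assoLwu5-1 with assoLwu5-2, and assoLmin43, assoLmin48 and assoLmin60 with the minyou accession of the same number. Their profiles were not clearly more alike than those of random couples: the mean correlation of centred profiles was 0.123 ± 0.228 (SD, n = 7), against -0.002 for random couples (one-sided permutation test, p = 0.0759). The highest were 0.373 for the couple of assoLwu, 0.350 for that of assoLmin43 and 0.331 for that of assoL213, and the lowest was -0.154 for that of assoLmin60. In none of the 7 couples was the partner the closest profile; the best rank was 8 of 220. The permutation p was 0.0408 without the couple of assoL164 and 0.0385 without that of assoLmin60, the couples with the lowest correlations. Leaving out any other couple gave a permutation p from 0.0666 to 0.185. With the first 2 components removed the mean was 0.0997 (permutation p = 0.012), which rested on the couples of assoLwu5-1 and assoLmin48, since leaving out either couple gave permutation p = 0.083 and 0.103.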

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

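The values below each lay far from the other accessions of their series, by Dixon's gap test in series of 4 to 10 accessions. Of the combinations of series and value examined, 11 or 9.48% stood out, where chance alone gives about 1 in 20. The set scores among them were chosen after the data were seen. No explanation was tested for any of these values.

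In the series of 4 digits, assoL3038 had a set 3 score of 2.13, against -1.29 for the median of the other 7 accessions, close to the mean of 1.89 of the minyou accessions. In log2(FPKM + 1) it had 6.55 for gene 1524.55 and 5.82 for gene 1493.24 of scaffold 12, where the medians of the others were 2.23 and 1.14. For genes 343.20 and 1044.6 of scaffold 3 it had 5.41 and 4.53, against medians of 1.43 and 0.15. All 4 genes belong to set 3, so the values are not independent. assoL3009 of the same series had the highest depth factor of the panel, 80.4, against 32.9 to 52.2 in the others.

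In gan, assoLgan2 had a set 2 score of 3.06, against a median of -1.52 for the others, and 8.43 for gene 650.26 of scaffold 6 in log2(FPKM + 1), against 3.08. The depth factor of assoLgan9 was 39.6, against 45.9 to 50.7. In Fy, assoLFy1 had a set 1 score of 0.41 against a median of -1.32 in the others, and assoLFy7 a set 5 score of 1.79 against 1.00.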

How the results depend on the processing

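No paired analysis was possible because replicate numbers follow accession order only and pair nothing. Of the results that answer a comparison, 53 alternative values kept their side of the threshold or, for counts and values with no test, stayed within 1.5 times or the spread, and 20 did not; of single genes and set scores, 195 kept side and direction, 12 lost significance and 2 gained it. No named gene and no set score past its threshold changed sign. Without the accessions of low correlation, some scores that had not passed changed sign and still did not pass. They were set 1 in tong (0.062), set 2 in the names of 4 digits (-0.28) and set 4 in gan (-0.017). Their adjusted p-values were 0.888, 0.779 and 0.97 (permutation test). Set 2 gained significance in minyou (1.03) and xiang (1.22) with depth as a covariate. The balance of higher and lower genes was less stable than the counts: lower genes became the majority in minyou and xiang under quantile normalization, the share of abundant genes or the first 2 components as covariates, and higher genes in tong under quantile normalization, that share, array weights and without the accessions of low correlation. With the first 2 components, 735 of the 800 minyou genes called with and without them kept their direction; under quantile normalization, 2326 of 2328. Depth as a covariate, the first component without its 20 most abundant genes, couples on partly silent genes and alternatives for set scores were chosen after the data were seen. Where accessions were left out, their smaller number may add to the changes below. The cause of these changes was not tested. Genes called against the numbered accessions: pseudocount 0.01 gave 1 for gan and 3 for the names of 4 digits, and quantile normalization gave 3 for the latter. The share of abundant genes as a covariate gave 1040 for minyou. The first 2 components as covariates gave 2231 for the F test, 325 for tong, 1237 for minyou and 1 for the names of 4 digits. Array weights gave 3350 for tong, 2701 for xiang and 371 for gan. Without the 29 accessions of low correlation the F test gave 2516, minyou 756 and xiang 666. Depth as a covariate gave 1079 for tong. Removing 2 components gave 0.0997 for the couples (p = 0.012). Partly silent genes made up 2.01% of all genes at 5% and 0.325% at 25% of accessions on each side. The median SD was 0.48 at pseudocount 0.1, and the first component held 21.6% without the 20 genes of highest panel mean. The minimum mean of 1 FPKM removed no gene, tests nothing and is not counted here. Count-based alternatives were not run, since the values are not counts. Absolute depth is unknown, so the precision of low values cannot be stated.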

Other observations

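All tests in this part were chosen after the result was seen, except those of the couples with 2 components removed and of depth on the partly silent genes. Series with fewer than 6 accessions were not tested, but some stood at the ends of the panel. Set 3 scores averaged 2.61 ± 0.73 in min (SD, n = 3), 2.59 ± 0.65 in guiruan (SD, n = 3), 2.36 ± 1.31 in gui (SD, n = 4) and 2.00 ± 1.03 in yawu (SD, n = 5), against -0.65 ± 0.87 in the numbered accessions. Set 5 scores averaged -4.80 ± 2.46 in min, -3.96 ± 0.84 in guiruan and -3.73 ± 3.94 in yawu, but 0.18 ± 2.12 in gui. Of these, 2 of 3 min, 2 of 3 guiruan and 3 of 5 yawu accessions, and 0 of 4 gui, are among the 29 accessions of low correlation. The closest profiles of the panel were assoLmin60 and assoLyawu4, with a centred correlation of 0.870.

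Genes close together in the gene index of a scaffold varied together slightly more than distant ones. Over 4098 gene pairs with the same index the mean correlation was 0.123, and over 7404 pairs 1 index unit apart it was 0.103, against 0.066 at more than 500 units. With the first 2 components removed these means were 0.083, 0.064 and 0.030. Of 1000 permutations of the positions within scaffolds none gave a mean above 0.077 for one index (p = 0.001, the smallest possible), which argues against chance placement. Pairs of genes are not independent replicates, and reads shared between neighbouring copies were not examined.

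The first component followed the share of the 20 most abundant genes. A difference in depth is argued against, since the component's correlation with the depth factor was -0.051. Dilution of all genes by the 20 genes of highest panel mean was not the whole source either. Without these, and with every accession rescaled to one total, the component still followed the share of each accession's own 20 most abundant genes (r = 0.841). Some genes counted in that share may stay in the rescaled values, so dilution by other abundant genes was not examined. Name series were not the whole source, since the correlation within the numbered accessions was 0.842. A difference in kernel maturity at harvest or in RNA quality may contribute; the labels record neither, no test here bears on them, and no biological explanation was tested.

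Genes silent in part of the panel lay near one another more often than random genes, though most had no such neighbour. Another lay within 10 index units for 32 of them, against a median of 17 and a highest count of 42 in 1000 random gene sets (comparison with random sets, p = 0.005). That argues against chance placement, and the 23 such pairs had a median correlation of 0.770. Too few reads in shallow accessions are argued against for the typical gene of the group, since the median rank correlation of the expressed state with the depth factor was 0.045. The depth factor does not hold the share taken by abundant genes. The number of genes at 1 FPKM or more fell with the share of the 20 most abundant genes (r = -0.769). Set 1, with 22 of the partly silent genes, fell with it too (r = -0.803). A part played by that share was not tested. Inherited presence or absence of short stretches of the genome is a candidate explanation that was not tested, and reads lost to sequence differences from the reference, or shared between copies, stay open.

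The name-matched couples were not clearly more alike than random couples. A likeness hidden by the first 2 components remains open: removing them gave p = 0.012, but leaving out either of 2 couples ended the call, a requirement added after the values were seen. The 3 couples highest before the removal, those of assoL213, assoLwu and assoLmin43, had 0.008, 0.017 and -0.076 after it. Mixed-up labels and names that mark unrelated trees were not tested.

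Whether random series give such counts was examined with 100 splits of the accessions into series of the same sizes, the real one included. In 1 of 100 splits, the real one, as many genes were found for the F test (4472, highest other 10), tong (1671, highest other 370), minyou (3636, highest other 5) and xiang (1277, highest other 454). That argues against chance for these 4 but, with only 100 splits, does not exclude it. For gan and the names of 4 digits, with 0 genes, the test is void: all 100 of 100 splits must give as many (highest other counts 135 and 2).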
